A study of Homo sapiens with 2 samples.

How the data were processed

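HCT116 cells were treated with a control siRNA or an SRSF3 siRNA, and RNA of 1 sample per group was hybridised to an Agilent 4x44K whole human genome array (design 014850). Per the labels' protocols, cRNA was amplified and labelled with Cy3 from total RNA. The number of cultures behind each RNA, the siRNA sequences and the time after transfection are not given in the sources used here. Groups were taken from the treatment label of each sample.

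Per the file headers, each array was quantified with Agilent Feature Extraction 9.5.3.1. The deposited scanner values are intensity per spot. The processed signal had the local background subtracted and a spatial trend removed by the scanner software, which gives dim spots a small positive value. The files also hold other values used here, the deposited flags of 0 or 1 per spot for well above background, saturated and outlier. A table of the whole series, deposited by the authors, holds a processed signal per probe and a log2 normalized value per probe. Its intensity columns equalled the mean of the scanner file's spots within 0.1% for 99.6% of probes on each array. In its log2 columns the values of both arrays mirrored each other around 0, with column medians of -0.066 for control siRNA and 0.066 for SRSF3 siRNA. Their difference departed from the log2 ratio of the signals by a constant of 0.186, close to the log2 ratio of the arrays' 75th percentiles, 0.194. The exact scaling and centring are not given in the sources used here. Column names of this table match the groups through the words for the siRNA, and the column for a random siRNA was read as the control.

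Each array had 45015 spots, 43376 of them not controls. Spots flagged as outliers (53 on the control array, 69 on the SRSF3 siRNA array) were removed, and the 1 saturated spot was kept. Values were log2 of the processed signal minus the array's 75th percentile over non-control spots, and spots of one probe were averaged on the log2 scale. A probe entered when it was well above background on at least 1 array, which held for 28122 of 40993 probes. A gene's log2 ratio was the median of its probes' ratios, and 63.0% of genes had 1 probe. Named genes with no probe well above background on an array, and such single probes where the text gives them, are bounds, while counts past 2-fold and list medians use measured ratios. The bounds set the brighter array's normalized value against the higher of the dim probe's own value and the lowest value of any probe well above background on that array. The precision is limited by the number of arrays, 1 per group. The scanner software's signal error was carried into each log2 ratio and is called the array error.

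Probes were named through the transcript accessions and symbols of the files and a RefSeq gene table on assembly GRCh38.p14. The accession matched for 23958 probes, the current symbol for 2755 and an older symbol for 1024. The file's own name was kept for 2070, and 11193 had no gene name. The array's annotation uses hg17, so no coordinate from the RefSeq table is printed.

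With 1 array per group no test across samples was possible, and no p-value is given. Genes were counted by a fixed size of 2-fold. For each of 30 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. A list was said to lie outside when its percentile was below 2.5 or above 97.5. Lists, thresholds, most other settings and the rule for named genes were fixed before the data were examined. The rule took SRSF3 and the 10 highest and 10 lowest genes with a RefSeq mRNA probe, all probes well above background on both arrays, of one sign and unsaturated, and a mean signal above the median. From each list it took up to 2 members past 2-fold each way, or else the member with the largest ratio. It also took the genes CCND1, CCND3, CCNE1, CCNE2, E2F1, E2F7, CDKN1A and HIPK2, and the 5 brightest genes seen on 1 array only. The lists covered splicing (SR proteins, hnRNP proteins, core spliceosome, mRNA export, SR protein kinases and phosphatases), the cell cycle (G1 to S, CDK inhibitors, DNA replication, G2 and mitosis, histones), p53 targets and cell death, and stress, interferon, NF-kappaB and immediate-early responses. The rest covered Wnt targets, metabolism, ribosomal proteins, autophagy, epithelial, mesenchymal and intestinal genes, and markers of other cell types.

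The other settings fixed in advance were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, scaling to the median of probes measured on both arrays, the authors' deposited log2 values, stricter and no filters on dim probes, the brightest probe or the mean per gene, other fold thresholds, a signal floor, and unmatched random lists. The files lack a mean spot signal, so normexp was run on the median spot signal and the median background. Settings added after the data were seen removed a lowess trend on mean signal (fraction 0.3), removed the median of each of 140 blocks of the array, set probes not well above background on 1 array to their bound, or left out list members. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

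The steps were tested on simulated data with spot noise drawn from repeated spots. Both simulated arrays were drawn from the control array, so noise between arrays or labellings was not part of the test. Of 14558 simulated genes, 50 were changed at each of the log2 ratios 1.5, -1.5, 2.5 and -2.5, and all 50 passed 2-fold at each size, with 0 calls among 14358 unchanged genes, all of them measured on both simulated arrays. The changed genes were all above the median signal, so recovery of dimmer genes was not checked. Calls of genes seen on 1 array only were not simulated. For lists of 30 genes, 20 of 20 lists shifted by 0.4 and 1 of 40 unshifted lists lay outside the random range.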

Results

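Total RNA of HCT116 cells, an established human colorectal carcinoma line, was measured after transfection with a control siRNA or with an siRNA against SRSF3, a member of the SR family of splicing factors. Each group had 1 sample on 1 one-colour (Cy3) whole-genome oligonucleotide array. Each array held 41000 gene probes, of which 264 were repeated on 10 spots. On the control array 67.7% of the 43376 non-control spots were well above background, with a 75th percentile signal of 942. The SRSF3 siRNA array had 67.4% and 824. No replicate was measured in either group, so no difference below has a replicate check. Ratios are SRSF3 siRNA over control siRNA on the log2 scale, and a gene was counted as higher or lower only when it passed 2-fold. The error printed with a gene is the scanner software's own estimate, and covers neither cultures nor labelling. It was near 0.20 for bright genes whatever their ratio, so it does not measure the spread between those spots. The array was annotated on the hg17 build, whose coordinates were not used here, so genes are given by symbol and transcript accession without coordinates. Members of a gene list that the rule for named genes did not select are given as log2 ratios and were chosen after their values were seen.

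The comparison asked which transcripts differ between HCT116 cells given an SRSF3 siRNA and those given a control siRNA. No other siRNA treatment against SRSF3 was measured, so effects of lower SRSF3 cannot be told apart from off-target effects of the siRNA. The targeted gene itself, read by 1 probe for NM_003017, had a processed signal of 62726 on the control array and 7635 on the SRSF3 siRNA array, 7.18-fold lower (log2 ratio -2.84, array error 0.20). Cell-cycle genes lay lower with it: E2F1, a transcription factor that drives S-phase genes, was 4.64-fold lower, cyclin D1 (CCND1) 3.47-fold lower and cyclin E1 (CCNE1) 3.22-fold lower. Nicastrin (NCSTN) and presenilin 2 (PSEN2), subunits of the gamma-secretase protease, were 5.85-fold and 4.15-fold lower. The other subunit genes looked at, given at the end, were within 2-fold. Genes of the integrated stress and unfolded protein response, epithelial genes and respiratory-chain genes lay higher as groups, and autophagy genes did so except under normexp or with dim probes kept. Among single bright genes with a RefSeq mRNA, GNB1L was 4.65-fold higher and ESRP1, an epithelial splicing regulator, 3.82-fold higher.

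Among 14849 genes well above background on at least 1 array, 510 had a measured ratio at least 2-fold higher and 453 one at least 2-fold lower. Of these, 188 and 136 were well above background on 1 array only, and only 94 and 56 of them passed 2-fold by their bound as well. With every probe not well above background on 1 array set to its bound, the counts were 395 and 355. Among the 13895 genes with all probes well above background on both arrays the counts were 282 and 283, together 4.07%, and 65 and 58 passed 3-fold. In the brighter part of these genes, above their median signal, 57 were higher and 66 lower. With the normexp background correction in place of the scanner's processed signal, the counts over all genes were 106 and 104. Under normexp 22 of the genes named here came inside 2-fold. That setting adds 50 to each spot, where median signals were 92 on the control array and 80 on the SRSF3 siRNA array. The offset by itself shrinks ratios of dim probes, so the lower counts do not reflect background correction alone. As a measure of spot noise, ratios of repeated spots of one probe had an SD of 0.11 around their probe's mean, and 1 of 2091 such spot pairs deviated by 2-fold.

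**Figure D1:**
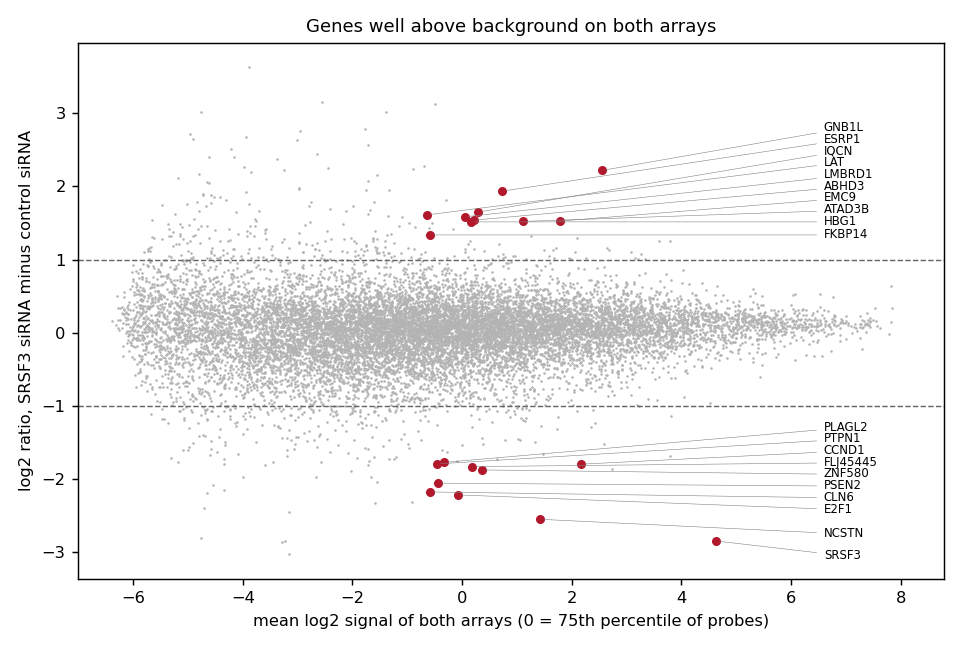
Log2 ratio (SRSF3 siRNA over control siRNA) of each gene well above background on both arrays, against its mean normalized log2 signal, with dashed lines at 2-fold and the named lowest and highest genes marked. Of the named genes SRSF3 lies lowest at -2.84 and GNB1L highest at 2.22, and some unmarked, mostly dimmer genes lie further out.

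Among bright genes with a RefSeq mRNA and probes of one sign, the 10 with the lowest ratios were SRSF3, NCSTN, E2F1, CLN6, PSEN2, ZNF580, FLJ45445, CCND1, PTPN1 and PLAGL2, with log2 ratios from -2.84 to -1.77. PSEN2 had 3 probes, at -2.09, -2.05 and -1.87. CLN6, an endoplasmic reticulum membrane protein mutated in a neuronal ceroid lipofuscinosis, was 4.51-fold lower, and PTPN1, the tyrosine phosphatase PTP1B, was 3.46-fold lower. The 10 with the highest ratios were GNB1L, ESRP1, IQCN, LAT, LMBRD1, ABHD3, EMC9, ATAD3B, HBG1 and FKBP14, with log2 ratios from 2.22 to 1.34. LAT, an adaptor of T-cell receptor signalling, had 3 probes, at 1.78, 1.61 and 1.40. LMBRD1, a lysosomal protein of cobalamin export, had a log2 ratio of 1.59, and EMC9, a subunit of the endoplasmic reticulum membrane complex, was 2.88-fold higher. The probes of HBG1, a fetal gamma-globin gene, cannot be assumed to separate it from its near-identical neighbour HBG2.

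Genes of the G1 to S transition were lower as a group. The 24 measured regulators had a median log2 ratio of -0.27, at percentile 0.01 of 10000 random lists matched on signal, with 6 members at least 2-fold lower, 0 higher and 21 below 0. E2F1 stood at -2.21 by its 1 probe (NM_005225), and CCNE1 at -1.68 (NM_001238). The 3 probes of CCND1 (NM_053056) read -2.02, -1.80 and -0.79. The remaining 3 of the 6 were cyclin D3 (CCND3), at -1.20 with probes at -1.26 and -1.14, the phosphatase gene CDC25A at -1.06, and the atypical E2F factor E2F7 at -1.03. Under normexp CCND3, CDC25A and E2F7 came to -0.90, -0.99 and -0.93, short of 2-fold. CCNE2 had a ratio of 0.036 and SKP2, a subunit of the ubiquitin ligase that targets p27, 0.88. The bright probe of MYC read -0.34 and a dim probe 0.59. Of the 8 CDK inhibitors, only CDKN2B passed 2-fold by its measured ratios, and no longer did with its dim probe at a bound: 1 probe read 1.12 and the other, not well above background on the control array, was at least 1.71-fold higher. The list's median was -0.025, at percentile 24.4. CDKN1A, encoding p21, had probes at 0.27 and 0.50, within 2-fold.

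**Figure D2:**
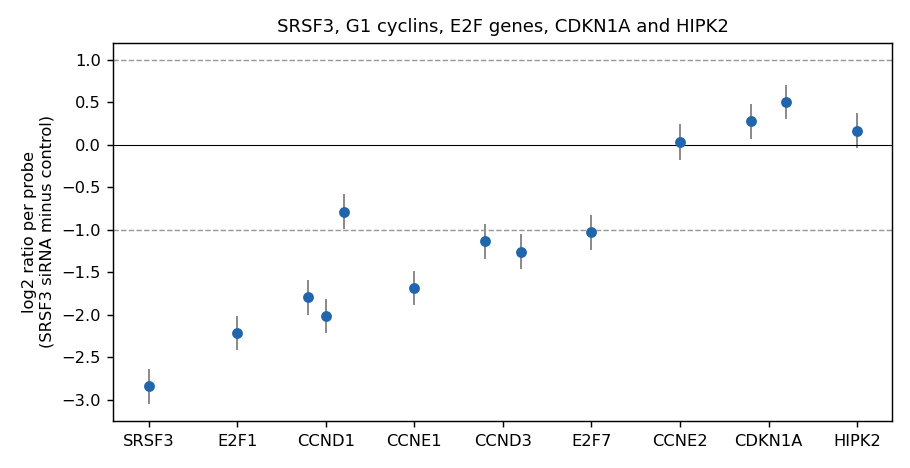
Log2 ratio (SRSF3 siRNA over control siRNA) of each probe of the G1 genes, CDKN1A, HIPK2 and SRSF3, with bars for the scanner software's error of the ratio on 1 array per group. E2F1, CCNE1 and CCND3 lie past 2-fold by every probe, while the probes of CCND1 range from -2.02 to -0.79.

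DNA replication genes showed the lowest median of the 30 lists. The 48 measured members had a median of -0.43, below all 10000 random lists, and 47 of them lay below 0, although only DSCC1, a subunit of an alternative clamp loader, passed 2-fold, at -1.03. The replication fork helicase gene CDC45 stood at -0.996, UHRF1 at -0.98, and the MCM helicase genes MCM5 and MCM2 at -0.92 and -0.90. The exception was DBF4, whose bright probe read -0.27 and whose dim probe read 0.82. The 44 genes of G2 and mitosis had a median of -0.35, again below all random lists, with 40 below 0. KIF20A, a mitotic kinesin, at -1.46 and ANLN, a cytokinesis scaffold, at -1.03 were at least 2-fold lower and 0 were higher. Cyclin A2 (CCNA2) had -0.98 and MKI67 -0.84, while CDK1 had 0.23. Without the members at least 2-fold lower, the medians were -0.20 for the G1 to S list, -0.43 for replication and -0.33 for mitosis. Replication-dependent histones had a smaller shift, a median of -0.11 over 51 genes at percentile 0.81, with 1 gene at least 2-fold higher, H4C16, 0 lower and 31 below 0. The histone list was within the random range with the brightest probe per gene, at percentile 2.67, and with dim probes kept, at 6.72.

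The splicing-factor lists lay lower by small amounts. The 24 hnRNP genes, which encode RNA-binding proteins that act on pre-mRNA, had a median of -0.19, below all random lists, with 17 below 0. Of these, only PTBP1, the polypyrimidine tract binding protein, was at least 2-fold lower, at -1.75 (NM_002819, array error 0.21). HNRNPL had -0.99. The 19 SR and SR-related genes had a median of -0.14 at percentile 0.71, and -0.14 without SRSF3 at percentile 1.08. Apart from SRSF3 all 18 were within 2-fold, from SRSF2 at -0.55 to SRSF9 at 0.22, with TRA2B at -0.48 among them. The 41 core spliceosome genes had a median of -0.030 at percentile 0.61, because random lists of equally bright genes lay higher. It ranged from -0.087 with the signal trend removed to -0.014 with the brightest probe per gene, and all 41 were within 2-fold, including DHX8, an RNA helicase of spliceosome release, at -0.73. Against random lists not matched on signal, the SR and core spliceosome lists were inside the random range, at percentiles 4.21 and 12.9. The 15 SR protein kinases and phosphatases had a median of 0.16 at percentile 84.9. Here CLK3 had -0.93, CLK1 0.83 and CLK4 0.77, all within 2-fold, and HIPK2 had 0.17 by 1 probe, which does not tell its isoforms apart. The 20 mRNA export genes had a median of -0.013 at percentile 18.5. NUP98, a nuclear pore protein, was the 1 member past 2-fold, but its 3 probes read -1.21, -1.06 and 0.97. The lower probes were annotated to the same transcript and the higher probe to another.

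Genes of the integrated stress and unfolded protein response were higher as a group, with a median of 0.30 over 29 genes, above all 10000 random lists, and 24 above 0. At least 2-fold higher were HSPA5, the endoplasmic reticulum chaperone BiP, with probes at 1.51 and 0.50, and SEL1L, an adaptor of endoplasmic reticulum degradation. The median of the HSPA5 probes, 1.01, came to 0.95 under quantile normalization, short of 2-fold. SEL1L rested on a dim probe, at least 3.38-fold higher, while its probe measured on both arrays read 0.37. DNAJB9 had 0.82, CHAC1 0.73 and HERPUD1 0.68. Against the group, the transcription factor gene ATF5 was at least 2-fold lower at -1.19, or -0.99 under normexp. ASNS had a bright probe at 0.071 and a dim one at -1.09. The 18 heat shock genes had a median of 0.19 at percentile 96.0, inside the random range, and 0 passed 2-fold, DNAJB4 at 0.86 having the largest ratio. The heat shock list lay above that range with the signal trend removed, with the brightest probe and with the mean over probes.

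Epithelial junction and keratin genes had a median of 0.29 over 25 genes, at percentile 99.9, with 20 above 0. ESRP1 at 1.94 and TJP3, a tight junction scaffold, at 1.13 were at least 2-fold higher and 0 were lower. E-cadherin (CDH1) had 0.59, CLDN7 0.67 and KRT19 0.65, while KRT20, not well above background on the SRSF3 siRNA array, was at least 1.63-fold lower. The 19 mesenchymal and matrix genes had a median of -0.039 at percentile 25.1, with all 19 within 2-fold, among them TWIST1 at -0.76. The 15 intestinal differentiation genes measured, of 30 listed, had a median of -0.078 at percentile 25.6, and only CEACAM1, a dim gene at -1.10, passed 2-fold. The respiratory chain list had a median of 0.22 over 46 genes, at percentile 99.99, with 43 above 0. It was 0.13 under quantile normalization, at percentile 99.97. SDHD, a subunit of succinate dehydrogenase, was at least 2-fold higher by all 4 of its probes, from 1.05 to 1.17, and SDHA had -0.53. Autophagy and lysosome genes had a median of 0.21 over 25 genes at percentile 98.8, with 19 above 0. WIPI1 at 1.30 and MAP1LC3B, which encodes LC3B, at 1.04 were at least 2-fold higher, and the cargo receptor SQSTM1 had 0.80. The MAP1LC3B probes read 1.08, 1.04 and 0.66, and the brightest was the one at 0.66, short of 2-fold. With normexp or with dim probes kept, this list lay at percentiles 95.7 and 96.4, inside the random range.

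**Figure D3:**
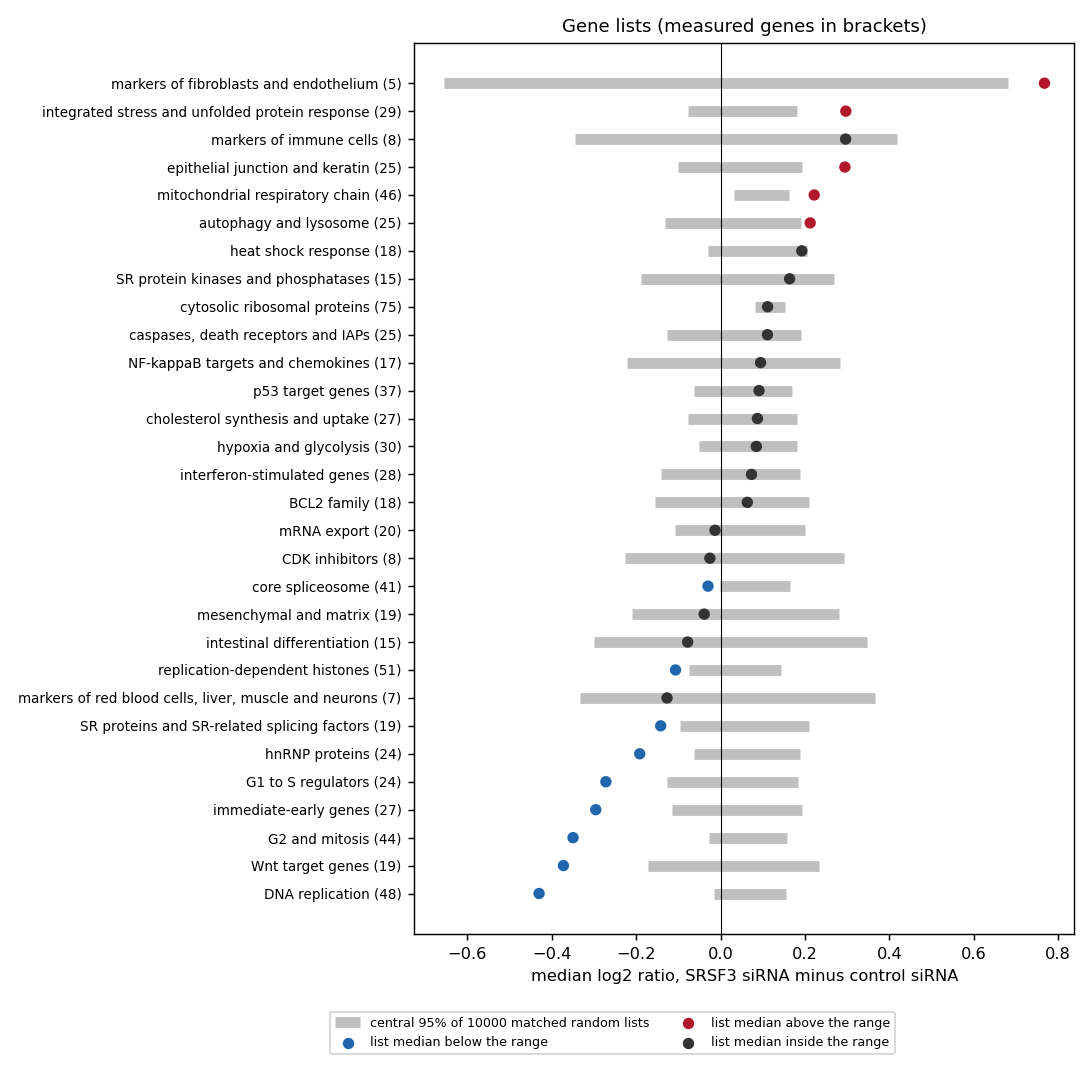
Median log2 ratio (SRSF3 siRNA over control siRNA) of each of the 30 gene lists as a point, with the number of measured genes in brackets and the central 95% of 10000 signal-matched random lists as a grey bar. The medians run from -0.43 for DNA replication to 0.77 for markers of fibroblasts and endothelium, which hold 5 genes.

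Wnt target genes had a median of -0.37 over 19 genes, below all random lists, with 14 below 0. Under normexp it was -0.19, at percentile 0.11. CCND1 was the 1 member past 2-fold, NKD1, a dim gene, had -0.83, and ASCL2, not well above background on the control array, was at least 1.45-fold higher. Immediate-early genes had a median of -0.30 over 27 genes at percentile 0.01, with 20 below 0, and of -0.18 at percentile 0.04 under normexp. EGR3 was at least 1.25-fold lower, since it was not well above background on the SRSF3 siRNA array. DUSP6 had -0.63, EGR1 -0.38 and FOSB 0.88.

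Lists tied to p53 and cell death were within the random range, except that the caspase list lay above it with the brightest probe per gene. The 37 p53 target genes had a median of 0.091 at percentile 69.4. The 1 member past 2-fold was POLH, a translesion DNA polymerase, with 1 probe at -2.30 and another, not well above background on the SRSF3 siRNA array, at least 1.55-fold lower. GDF15 had 0.53 and MDM2 -0.086. The BCL2 family had a median of 0.063 over 18 genes at percentile 58.1, with BCL2A1 at 1.06 and BCL2L11, which encodes BIM, at -1.13, the median of 5 probes, 1 of them not well above background on the SRSF3 siRNA array. The brightest BCL2L11 probe read -0.93, inside 2-fold, and the others were much dimmer. Caspases, death receptors and inhibitors of apoptosis had a median of 0.11 over 25 genes at percentile 80.1, and all 25 were within 2-fold, BIRC6 at -0.86 and TNFRSF1A at 0.74 among them. Interferon-stimulated genes had a median of 0.073 over 28 genes at percentile 66.9, with IFI27 at 1.34 and ISG20 at 1.04 at least 2-fold higher and OAS3 at -0.86. NF-kappaB targets had a median of 0.095 over 17 genes at percentile 65.9, and LCN2 was at least 1.35-fold higher. Cholesterol genes had a median of 0.087 over 27 genes at percentile 65.4, with HMGCS1 at 1.02. Hypoxia and glycolysis genes had a median of 0.085 over 30 genes at percentile 55.2, and SLC2A3 was at least 2.64-fold lower. The 75 cytosolic ribosomal protein genes had a median of 0.11 at percentile 43.6 with all within 2-fold, up to RPL22 at 0.42.

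Most markers of cell types that do not belong to the line were dim or not measured. Of 15 immune markers 8 were measured, with a median of 0.30 at percentile 90.6 and CD8A at -1.01. Of 14 markers of fibroblasts and endothelium 5 were measured, with a median of 0.77 at percentile 98.5 and CDH5 at least 1.60-fold higher. That median rested on genes near the background: with dim probes at their bounds it was 0.53, at percentile 96.4 and inside the random range, and over probes well above background on both arrays it was -0.052, at percentile 37.9. ACTA2 had -1.59, and of the 2 probes of VWF 1 read -0.63 and the other, not well above background on the control array, was at least 2.37-fold higher. Of 14 markers of red blood cells, liver, muscle and neurons 7 were measured, with a median of -0.13 at percentile 15.1, HBB at -1.63 and ALB at least 3.15-fold higher. In all, 14 of the 30 lists lay outside the central 95% of random lists, 9 below and 5 above, where chance alone would place 1.5. Of the 16 lists inside that range, 5 had medians of no settled sign, turning under at least 1 other setting: SR protein kinases and phosphatases (to -0.061 with the brightest probe), CDK inhibitors, mesenchymal, intestinal, and the markers of red blood cells, liver, muscle and neurons. Lists share members and genes within a list are not independent, so percentiles describe these 2 arrays.

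Some genes were well above background on 1 array only, 286 on the control array and 292 on the SRSF3 siRNA array. The brightest on the control array were RFX4, at least 11.3-fold lower after SRSF3 siRNA, ZG16B at least 10.99-fold, TLL1 at least 9.72-fold, ZNF93 at least 8.35-fold and HEPACAM2 at least 7.88-fold. On the SRSF3 siRNA array they were TMEM229B, at least 16.6-fold higher, H4C16 at least 12.9-fold, CX3CR1 at least 11.8-fold, NPY6R at least 10.6-fold and RASAL3 at least 10.3-fold. Each of these bounds rested on 1 probe. With dim probes kept, RFX4 and ZNF93 turned direction, at 0.14 and 0.13.

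As SRSF3 acts in splicing, and probes of one gene can lie in different exons, ratios were also compared between probes of a gene. Of 5214 genes with at least 2 probes well above background on both arrays, 336 (6.44%) had probes whose ratios differed by 2-fold or more, and 33 by 4-fold or more. In 255 of the 336 the probes lay on opposite sides of 0, and in 7 genes one probe was at least 2-fold higher and another at least 2-fold lower. Under normexp the count fell to 129. Among genes with bright probes, NUP98 had the widest range, from -1.21 to 0.97, followed by SNX5 from -0.043 to 1.44, ESYT2 from -0.30 to 1.17 and DR1 from 0.30 to 1.72. These names were chosen after their values were seen.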

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

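Probes without a gene name stayed outside the gene counts and were looked at because the control array gives a level to compare with. Of 11191 such probes, 5298 were measured on both arrays. Among these, 174 were at least 2-fold higher after SRSF3 siRNA and 147 at least 2-fold lower. A further 272 were well above background on the SRSF3 siRNA array alone, against 300 on the control array alone. Among bright unnamed probes, picked after their values were seen, A_24_P456944 read -2.13 and A_24_P315921 read 1.75.

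The tests of array position, signal-dependent bias, noise of single probes and pseudogene copies were chosen after the result was seen.

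The lower DNA replication and mitosis genes were the first of 3 patterns weighed. Joined, the 92 genes had a median of -0.40, where random lists had 0.072. With each block's median removed from the array the median was -0.40, below the central 95% of random lists, which argues against position as the whole cause. With the trend on signal removed the median was -0.44, so that trend did not produce the lower values. Random lists were already matched on signal, so the place among them could hardly change and was no test of signal-dependent bias. Of the 92 genes 87 lay below 0, and random lists of equally bright genes, which carry the same noise of single probes, had medians from 0.0092 to 0.13 in their central 95%. The 2 lists were joined because each already lay below all random lists, so this outcome was fixed. It repeats the result that picked the pattern and adds no separate evidence on probe noise. The comparison with random lists replaced 2 earlier tests of agreement between probes of a gene. The outcome of the first was fixed by most members lying below 0. The second, in the few members with at least 2 probes, left noise of single probes open, and it was dropped for the random lists, which cover all members. A difference between the treatments, and one in density or transfection between the cultures, stay open and were not tested.

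Probes of one gene that differed by 2-fold or more were the second pattern, with 336 genes. Spot noise simulated from repeated spots gave 2 such genes, and at most 8 in 1000 simulations, which argues against noise between spots. Among 1424 genes with all probes bright, 20 differed (1.40%, Wilson interval 0.91 to 2.16) against 6.44% of all. This share lay below the limit set in advance for low signal as the cause, but its interval reached above that limit. Low signal may therefore account for much of the count, but this share did not settle it. The differing genes had 5.33 annotated transcripts on average, and matched random lists 5.92 (5.03 to 7.05), which leaves a splicing or 3' end difference neither favoured nor excluded. Probes that match an unintended transcript were not tested.

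The keratin family was the third pattern, with 53 genes at a median of 0.33, above all random lists, and 49 above 0. Pseudogene symbols made up 27 of them, with a median of 0.33. The 26 remaining genes had a median of 0.37 at percentile 99.95, which argues against pseudogene copies as the only source. With the trend on signal removed the family's median was 0.27, so that trend did not account for most of it. Random lists were already matched on signal, so the family's place among them could hardly change and was no test of signal-dependent bias. Cross-hybridisation from the very bright KRT19, KRT18 and KRT8 to the other probes stays open, as does a difference between the treatments, and neither was tested.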

How the results depend on the processing

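Each group has 1 array, so no replicate could be left out, and no paired analysis was possible because the groups hold no replicates to pair. Removal of the signal trend and of array position, dim probes at their bounds, lists without their lower members and the SR list without SRSF3 were tried after the data were seen. Causes of the changes below were not tested, though the normexp offset of 50 by itself shrinks ratios of dim probes. Higher and lower genes (510 and 453) came to 106 and 104 under normexp, 303 and 296 above background on both arrays, 395 and 355 with dim probes at bounds, 189 and 148 at 3-fold, and 58 and 66 above the signal floor; with no filter 777 were higher. Genes with differing probes (336) came to 129 under normexp and 33 at 4-fold. Of 364 list medians under alternatives, 350 stayed on their side of the random range, 12 changed sign and 48 moved by over 1.5 times without a change of sign. SR proteins (-0.14) and core spliceosome (-0.030) lost their place against unmatched lists, histones with no filter (-0.031) and the brightest probe (-0.088), autophagy under normexp (0.16) and with no filter (0.17). Fibroblast and endothelial markers lost theirs above background on both arrays (-0.052), with no filter (0.16), the brightest probe (0.53) and dim probes at their bounds (0.53). Caspases gained a place with the brightest probe (0.19), and heat shock with the trend removed (0.13), the brightest probe (0.22) and the mean (0.24). VWF reversed to -0.63 above background on both arrays and to -0.63 with the brightest probe, and with no filter RFX4 came to 0.14 and ZNF93 to 0.13. Of 1325 values of named genes under these settings, 1257 kept direction and side of 2-fold, 51 came inside 2-fold (22 under normexp), 13 passed it and 4 reversed. SRSF3 ranged from -2.94 to -2.84. Settings moved the median of all genes by -0.046 to 0.078. Dim genes carry least weight: spot SD was 0.23 in the dimmest bin of repeated probes and 0.042 in the brightest.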

Other observations

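The genes in this part were chosen after their values were seen. The gamma-secretase subunits did not move together. Beside NCSTN at -2.55 and PSEN2 at -2.05, the subunit gene APH1B had -0.86, APH1A -0.26 and PSENEN 0.30. The gene of the beta-secretase BACE1 was at least 2-fold higher at 1.15, and that of the sorting receptor SORL1 at least 2-fold lower at -1.31. Globin genes went both ways: the embryonic HBE1 had 1.14 and HBG1 1.52, HBA1 had -0.42 and the adult HBB -1.63. Heme oxygenase 1 (HMOX1), a gene of the oxidative stress response, had 1.26, and TRAM1, a protein of the translocon, 1.26. NEAT1, the noncoding RNA that scaffolds paraspeckles, is no mRNA and so fell outside the rule for named genes, and was at least 2-fold higher by both of its probes, at a median of 1.82.

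Gene families sharing a symbol prefix were also compared, 62 with at least 20 measured genes, of which 5 lay below and 2 above the central 95% of random lists, where chance alone would place 3.1. The 366 ZNF genes had a median of -0.072, below all random lists, with 15 at least 2-fold lower and 4 higher. The 32 KIF genes, kinesin motors, had -0.24 at percentile 0.06, with 3 at least 2-fold lower, 0 higher and 20 below 0. The 37 CEP genes had -0.20, the 41 KIAA genes -0.26, the 50 EIF genes -0.030 and the 27 DNAJC genes 0.21.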
